A study of Mus musculus with 2 samples.

How the data were processed

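Chromatin immunoprecipitation and sequencing (ChIP-seq) was carried out with an antibody against histone H3 dimethylated at lysine 4 (H3K4me2), a mark found at active and poised promoters and enhancers. The tissue was the facial prominence of B6NCrl mouse embryos at embryonic day 13.5, pooled from male and female embryos. Per the labels there were 2 biological replicates of this 1 group. Both replicates carry the same donor strain record, and the labels do not say how many litters each pool came from, so every SD given here measures the spread between these 2 pools. No treated, mutant or other-tissue group was part of the series, and no comparison between conditions was made.

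The authors deposited 4 peak lists in the narrowPeak format on the mm10 mouse genome. Per the README files deposited with the samples, 1 list was made for each replicate from its own alignments, 1 list was made from the alignments of both replicates together (the pooled list), and 1 list was derived from the pooled list and both replicates' lists (the replicated list). Every entry of the replicated list was also an entry of the pooled list. Not all of them were peaks of both replicates: 3098 (7.38%) did not overlap a peak of each replicate by 50% of either, and 77 overlapped neither replicate. The deposited lists gave each peak a score, which was not used here, an enrichment on a linear ratio scale, and a significance as −log10 of q. The enrichment was taken as the ratio of the ChIP to the control, the usual content of that column, and the labels name a control experiment for both replicates. These values per peak are the authors' own and were used only to describe, rank or filter peaks within a list. The peak caller, its threshold and the rule by which a peak counted as replicated are not given in the sources used here. The largest q in the deposited lists was 0.412 in replicate 1 and 0.400 in replicate 2, so the lists were not limited to peaks of small q. Read counts were not analysed here, so the sequencing depth of each replicate is unknown and no interval that rests on depth is given.

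Coordinates were compared with the GRCm38.p6 sequence and the GENCODE M21 annotation, which use the same chromosome coordinates as mm10. The last peak lay within the reference length of each of the 21 chromosomes. Of the 1000 pooled peaks of smallest q, 93.8% touched a promoter window, against 14.2% for windows moved by 1 Mb. Peaks on unplaced or unlocalized scaffolds were left out of every comparison with the annotation. Coordinates are given counting from 1.

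Replicates were compared by the share of each replicate's peaks that overlapped a peak of the other by at least 1 bp. Each replicate's peaks were also placed at random on their own chromosomes 100 times. Enrichment was compared across shared peaks with Spearman's rho. Peaks are not independent replicates, and no p-value is given for rho. Each peak was assigned to a promoter (within 1000 bp of the transcription start site, TSS, of a protein-coding transcript), otherwise to an exon, an intron or intergenic sequence of protein-coding genes. A gene was called marked when a peak of the replicated list lay within 1000 bp of the 5′ end of its gene record, over 21911 protein-coding genes. That 5′ end can lie upstream of the promoter in use, and marked genes were therefore also counted at any annotated transcript's TSS. The width of a marked region was the number of bases covered by peaks within 5000 bp of the TSS, at most 10001.

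Gene lists for the tissues and cell types a facial prominence sample could hold, for other organs and for gene families were fixed before the data were examined, as were the motifs and the 2 tests of each list described here. Tests chosen later are given as such where they are used. There were 17 lists of written genes and 11 families taken by gene symbol. One gene of the red blood cell list was missing from the annotation. The marked members of each list were compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. The median width of each of the 23 lists with at least 5 marked members was compared with 100000 random lists of the same size among marked genes by a permutation test, two-sided, with the same adjustment over those lists. The smallest unadjusted p these permutations can give is 2.0e-05. An adjusted p below 0.05 was called. Genes are not independent replicates, so these tests compare genes within these libraries.

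Distal peaks lay over 5000 bp from the TSS of any annotated transcript. The density of 15 transcription factor consensus sequences in distal peaks was divided by that in flanks of the same length placed 5000 bp away, outside peaks and away from TSSs. Each ratio was ranked among up to 100 rearrangements of the same letters with as many CpG dinucleotides. A consensus needed at least 20 sites in the flanks and 5 usable rearrangements, and the latter limit was lowered from 20 after the first run, which admitted the homeodomain consensus. The remaining 14 were reported.

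Named genes were chosen by rule. For each list these were the 3 members with the most covered bases and up to 3 unmarked members in alphabetical order. Over all genes they were the 10 with the longest peak region across the TSS after joining peaks up to 1000 bp apart. The 5 distal peaks of highest enrichment were named with the nearest protein-coding gene, and for each replicate the 3 peaks of highest enrichment without a partner. A few further genes that make up small counts are named outside this rule and were chosen after their values were seen. To weigh CpG content at the promoter, each member of a list was replaced by a random gene from the same CpG bin, 10000 times. The 20 bins were of observed over expected CpG within 1000 bp of the TSS.

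Alternatives covered the overlap that counts as shared, q of at most 0.01, equal numbers of top peaks, the pooled list, each replicate's own list, TSS windows of 500 and 2500 bp, all annotated genes or transcripts, a width window of 10000 bp and a distal limit of 20000 bp. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The tests were tried on simulated data before use. Of 200 random lists of 16 genes, 4.0% had an unadjusted p below 0.05 in the TSS test, against 100% of 200 lists with every member marked. In the width test 4.5% of 200 random lists of 16 marked genes had such a p, against 58.0% of lists drawn from the upper 50% of widths and 100% of lists drawn from the upper 25%.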

Results

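H3K4me2 peaks were mapped in facial prominence tissue at embryonic day 13.5, when the upper and lower jaw, palate and nose are forming from neural crest mesenchyme covered by epithelium. The data were 2 biological replicates of 1 group. Replicate 1 had 53220 peaks and replicate 2 had 55159, a mean of 54190 ± 1371 (SD, n = 2). Their peaks covered 57.2 ± 0.94 Mb (SD, n = 2), or 2.1% of the genome. The pooled list held 59371 peaks and the replicated list 42003, which covered 60.1 Mb. The comparisons open to this design were between the replicates, between regions of the genome and between groups of genes.

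The strongly enriched H3K4me2 sites were the same in both replicates, and the peaks found in 1 replicate were mostly weak and short. In replicate 1, 80.8% of peaks overlapped a peak of replicate 2, and 77.8% did so in the other direction (79.3% ± 2.16, SD, n = 2). Randomly placed peaks overlapped in 4.20% and 4.10% of cases. Promoter peaks were shared most often, in 96.4% of replicate 1 peaks and 95.5% of replicate 2 peaks, and intronic peaks least often, in 67.2% and 61.8%. With each replicate's peaks in 10 equal bins by enrichment, every peak in the 4 highest bins had a partner, whereas in the lowest bin 43.4% of replicate 1 peaks and 39.4% of replicate 2 peaks did. Unshared peaks had a median enrichment of 3.05 in replicate 1 and 3.01 in replicate 2, against 8.07 and 8.87 for shared peaks. Their median lengths were 243 and 239 bp, against 841 and 871 bp for shared peaks. An overlap of 1 bp is easier to reach for long peaks. Across the 43002 shared peaks of replicate 1, Spearman's rho of enrichment was 0.84.

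**Figure D1:**
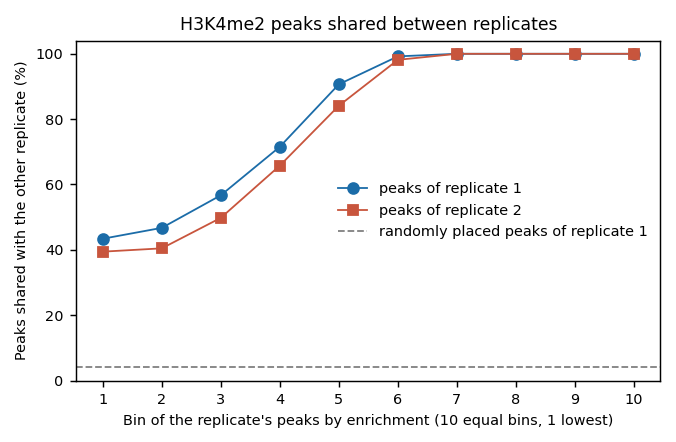
Share of each replicate's H3K4me2 peaks that overlapped a peak of the other replicate (vertical axis, %) in 10 equal bins of enrichment within that replicate (horizontal axis), with circles for replicate 1, squares for replicate 2 and a dashed line for randomly placed peaks of replicate 1. Sharing rose from 43.4% and 39.4% in the lowest bin to 100% in the 4 highest, against 4.20% for random placement.

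The highest-ranked unshared peaks were of modest enrichment, though above the median of all peaks in their replicate (5.22 and 5.18). In replicate 1 they lay on chromosome 11 from 108377790 to 108378220 in an intron 33862 bp from the nearest protein-coding gene TSS, that of Prkca (enrichment 6.47), on chromosome X from 159459133 to 159459626 (nearest gene Map7d2, 6.41) and on chromosome 10 from 67106794 to 67107158 (intronic, nearest gene Reep3, 5.93). In replicate 2 they lay on chromosome 8 from 77009208 to 77009753 (intronic, nearest gene Nr3c2, 7.43), on chromosome 4 from 6514972 to 6515296 (intergenic, nearest gene Nsmaf, 7.19) and on chromosome 5 from 24077857 to 24078172 (intergenic, nearest gene Klhl7, 7.19). All of these peaks overlapped a pooled peak.

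H3K4me2 was concentrated at promoters. Of the replicated peaks on assembled chromosomes, 39.2% touched a promoter window, 7.81% an exon, 22.2% an intron and 30.8% intergenic sequence. Promoter windows made up 2.37% of the genome but held 44.5% of peak bases, an 18.8-fold excess, while introns held 0.86 times and intergenic sequence 0.34 times their share of the genome. In the replicates' own lists 33.6% ± 0.24 of peaks (SD, n = 2) were at promoters and 27.8% ± 0.24 in introns. Promoter peaks had a median enrichment of 31.8 and a median length of 2173 bp. Intronic peaks had a median enrichment of 4.02 and a median length of 589 bp, and intergenic peaks 5.31 and 684 bp.

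Of 21911 protein-coding genes, 14248 (65.0%) were marked. The replicates' own lists marked 14323 and 14341 genes (14332 ± 12.7, SD, n = 2), and 98.0% of genes marked in either were marked in both. Of the unmarked genes, 87.6% had no covered base within 5000 bp of the TSS. Of the 28 gene lists, 11 were marked more often than other genes, 7 less often, and 10 passed no threshold.

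Every regulator of facial mesenchyme on the list was marked, 31 of 31, in the replicated list and in each replicate (adjusted p = 1.1e-05, Fisher's exact test; 65.0% of other genes). They included Msx1, needed for palate and tooth development, Gsc, Lhx8 and Meis2. Signalling genes of the face were marked in 29 of 30 cases (adjusted exact p = 1.8e-04), among them Pdgfra, a receptor of neural crest mesenchyme, Lef1, a mediator of Wnt signalling, and Spry2, an inhibitor of FGF signalling. Oral and surface epithelium genes were marked in 23 of 24 cases (adjusted exact p = 0.0018), with Tfap2c, Pitx2 and Cldn6 the widest. Neuronal genes were marked in 17 of 18 cases (adjusted exact p = 0.0096), with Isl1, Tubb3 and Nefm the widest and Phox2b unmarked. All of 19 Sox genes (adjusted exact p = 0.0010), 18 of 19 Wnt genes (adjusted exact p = 0.0096), 38 of 44 Fox genes (adjusted exact p = 0.0043) and 37 of 42 members of homeobox families of the head (adjusted exact p = 0.0021) were also marked. Of this last list, 20 members also stood in the facial mesenchyme list. Its unmarked members were Lhx3, Lhx4, Lhx5, Pax4 and Pax5. Lhx5 had a TSS peak in each replicate's own list, and Lhx3 had 1 in replicate 1's own list. At any annotated transcript's TSS 40 of 42 members had a peak, Lhx3 and Lhx4 among them.

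Housekeeping, ribosomal protein and Zfp genes were marked often too. Housekeeping genes had 23 of 24 members marked (adjusted exact p = 0.0018), cytosolic ribosomal protein genes 75 of 79 (adjusted exact p = 1.7e-09), and zinc finger genes named Zfp 313 of 365 (adjusted exact p = 2.3e-18). The unmarked ribosomal genes were Rpl10l, Rpl17, Rpl39l and Rpl3l. Rpl17, as well as Fgf10, Wnt8b, Ywhaz and Krt19, the only unmarked members of the signalling, Wnt, housekeeping and epithelium lists, had a peak at another annotated transcript's TSS. Of the 11 lists marked more often, 9 had a marked share inside the central 95% range of random lists matched on CpG content, and the epithelium list (range 66.7% to 91.7%) and the Zfp list (75.6% to 81.4%) lay above it. The facial mesenchyme range was 90.3% to 100%, and the upper bound was also 100% for the neuronal, signalling, Sox and Wnt lists. No share can exceed 100%, so for these lists the match could not show an excess over CpG content.

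**Figure D2:**
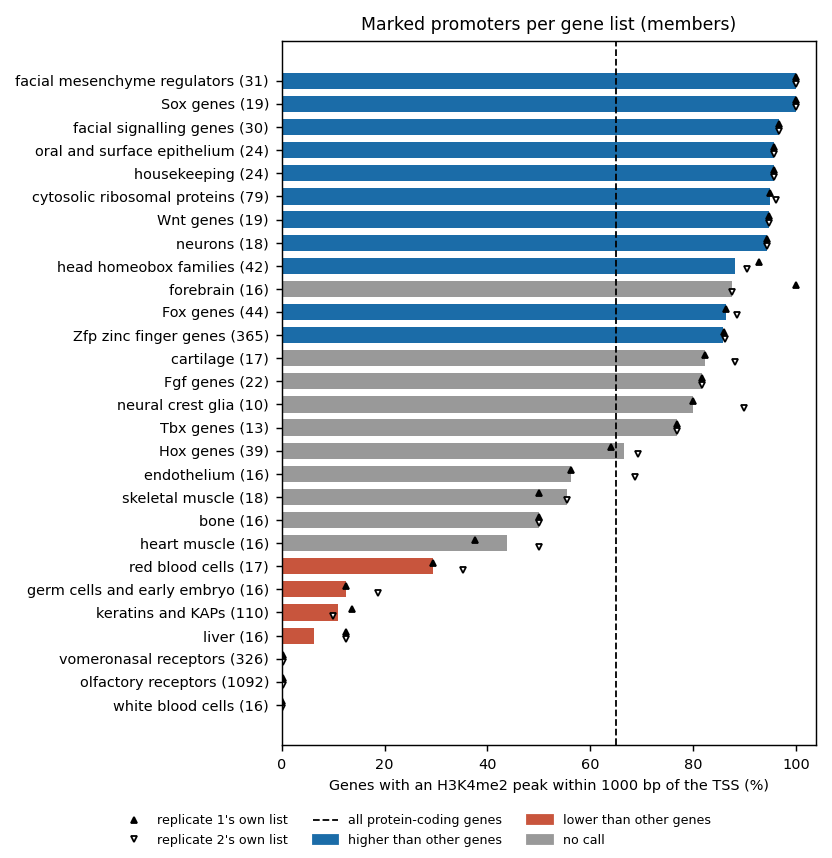
Share of the members of each gene list with an H3K4me2 peak within 1000 bp of the TSS (bars, %, replicated list; number of members in brackets), with triangles for each replicate's own list and a dashed line at 65.0% for all protein-coding genes. Bars are coloured by the call of Fisher's exact test, and run from 100% for the facial mesenchyme and Sox lists to 0% for white blood cells.

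Genes of white blood cells, liver, germ cells and sensory receptors were marked rarely. None of 16 white blood cell genes was marked in the replicated list or in either replicate (adjusted p = 2.3e-07, Fisher's exact test). Spi1, which encodes the myeloid regulator PU.1, and the complement genes C1qa and C1qb were among those unmarked. Cd68 had 5080 covered bases within 5000 bp but none of them within 1000 bp of its TSS, and Coro1a had a peak at another transcript's TSS. Liver genes were marked in 1 of 16 cases, Foxa3 (adjusted exact p = 6.1e-06), with Alb, Afp and Ahsg unmarked. Genes of germ cells and the early embryo were marked in 2 of 16 cases, Tdrd1 and Dazl (adjusted exact p = 6.9e-05), with Ddx4, Dppa3 and Dppa5a unmarked. Dppa3 had a peak at another transcript's TSS, and 3 of 16 genes of this list had a peak at any transcript's TSS.

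Red blood cell genes were marked in 5 of 17 cases (adjusted exact p = 0.0064), namely Epor, Nfe2, Tal1, Gypa and Klf1, while Gata1, Alas2 and Epb42 were unmarked. Their share of 29.4% lay inside the range of lists matched on CpG content (11.8% to 35.3%). Some globin genes of this list are near-identical copies whose reads are hard to place, so their unmarked state is uncertain. Keratin and keratin-associated genes were marked in 12 of 110 cases (adjusted exact p = 2.7e-31), and those of the embryonic epidermis, Krt14 and Krt15, were among the marked ones. Only 2 of 1092 olfactory receptor genes, Olfr1033 and Olfr658, were marked, with an adjusted p too small for the routine to represent. Of 326 vomeronasal receptor genes, Vmn1r4 was the only 1 marked (adjusted exact p = 1.6e-147). Receptors of both families also share sequence with close copies.

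The lists without a call had shares of 43.8% to 87.5%. They were cartilage (14 of 17), bone (8 of 16), skeletal muscle (10 of 18), neural crest glia (8 of 10), endothelium (9 of 16), forebrain (14 of 16), heart muscle (7 of 16), Hox (26 of 39), Tbx (10 of 13) and Fgf genes (18 of 22). Cartilage had Sox9, Sox6 and Col2a1 marked and Matn1 and Snorc unmarked, though Matn1 had a TSS peak in replicate 2's own list. Bone had Col1a1, Satb2 and Sp7 marked and the mineralization genes Bglap, Dmp1 and Ibsp unmarked. Skeletal muscle had Pax7, Tbx1 and Myf5 marked and Acta1, Actc1 and Chrna1 unmarked. Endothelium had Fli1, Erg and Esam marked and Cdh5 and Emcn unmarked. Glia had Sox10, Erbb3 and Ngfr marked and Plp1 and Cdh19 unmarked, though Cdh19 had a TSS peak in replicate 2's own list (9 of 10 marked). The glia share of 80.0% lay above the range of lists matched on CpG content (40.0% to 70.0%), as in no other list without a call. In heart muscle Hand1 and Tbx20 were marked and Myh6 and Mybpc3 were not. Forebrain had Emx2, Bcl11b and Six3 marked and Fezf2 and Neurod6 unmarked. The forebrain list passed the threshold in replicate 1's own list, with 16 of 16 marked (without replicate 2, adjusted exact p = 0.0042), and so did the heart muscle list, with 6 of 16 marked (adjusted exact p = 0.044, lower). The forebrain list also passed it in the pooled list (adjusted exact p = 0.025), with a 2500 bp window (0.043) and at any transcript's TSS (15 of 16, 0.042), and the Fgf list did at any transcript's TSS (20 of 22, adjusted exact p = 0.032).

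Of the 23 lists with enough marked members, the regulators of facial mesenchyme had the widest marked regions. Their median covered length was 7295 bp of the 10001 bp around the TSS, against 2750 bp for all marked genes (adjusted p = 7.7e-05, permutation test, which rests on the smallest p the permutations can give). In the replicates' own lists this median was 7157 ± 90.5 bp (SD, n = 2). Of the 31 genes, 30 lay above the upper quartile of marked genes, 3733 bp, and Prrx2 was the exception with 2422 bp. Gsc, Lhx8, Meis2, Msx1, Pax3 and Six2 were covered over all 10001 bp. In the replicates' own lists Gsc was covered over 9438 ± 625 bp and Pax3 over 9720.5 ± 188.8 bp (SD, n = 2). Random lists of the same size matched on CpG content had medians of 2413 to 3395 bp in the central 95%.

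Skeletal and signalling genes followed. The 8 marked bone genes had a median of 6626 bp (adjusted permutation p = 7.7e-05), with Col1a1 at 8197 bp, Satb2 at 7772 bp and Sp7, a regulator of bone-forming cells, at 7060 bp. Dlx5 and Satb2 of this list also belong to the facial mesenchyme list, and the other 6 marked bone genes had a median of 5698 bp. Signalling genes had a median of 5885 bp (adjusted permutation p = 7.7e-05), with Lef1 at 9843 bp and Pdgfra at 9505 bp. Cartilage genes had a median of 4429 bp (adjusted permutation p = 0.0042), with Sox9 at 7602 bp. The homeobox families of the head had a median of 6377 bp (adjusted permutation p = 7.7e-05), and 3360 bp over the 17 marked members outside the facial mesenchyme list.

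Smaller excesses were found for housekeeping genes (3874 bp, adjusted p = 0.0075), ribosomal protein genes (3356 bp, adjusted p = 0.0063), Fox genes (3558 bp, adjusted p = 0.0088), Sox genes (3947 bp, adjusted p = 0.0088) and Tbx genes (4203 bp, adjusted p = 0.024), all by the permutation test. The Fox median lay inside the range of lists matched on CpG content. The Sox call was lost in each replicate's own list (adjusted permutation p = 0.097 without replicate 1 and 0.055 without replicate 2), where its excess over all marked genes fell from 1197 bp to 715 and 812 bp. The Tbx call was lost without replicate 2 (adjusted permutation p = 0.055), with an excess of 1136 bp against 1452.5 bp. Among genes with no other protein-coding TSS within 10000 bp, chosen after seeing the data, the cartilage (adjusted permutation p = 0.060), housekeeping and ribosomal calls (both 0.14) were lost, while excesses of 1154.5, 797 and 489.5 bp remained, against 1679, 1124 and 606 bp among all marked genes. Wnt genes, at 3543 bp (adjusted permutation p = 0.072), missed the threshold and passed it in each replicate's own list (adjusted permutation p = 0.045 without replicate 1 and 0.046 without replicate 2), in the pooled list (0.0060), with a 10000 bp window (0.0065) and among genes with no other TSS within 10000 bp (0.040).

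Marked regions were narrow at 3 lists. Hox genes had a median of 1547 bp (adjusted p = 7.7e-05, permutation test), and their widest members were Hoxa7 with 2526 bp, Hoxa1 with 2298 bp and Hoxd3 with 2139 bp. Skeletal muscle genes had a median of 1362 bp over 10 marked genes (adjusted permutation p = 0.0011), with Pax7 at 8377 bp and Tbx1 at 6036 bp above it. Zfp genes had a median of 2356 bp (adjusted permutation p = 7.7e-05), with Zfp503 at 9598 bp, Zfp36 at 7885 bp and Zfp532 at 7752 bp at the other end. The keratin list, at 1999 bp (adjusted permutation p = 0.064), passed the threshold in replicate 1's own list (without replicate 2, adjusted permutation p = 7.7e-05), in the pooled list (0.0011) and with a 10000 bp window (0.019). The remaining lists without a call had medians of 3464 bp (epithelium), 3234 bp (endothelium), 3078 bp (forebrain), 2992 bp (glia), 2760 bp (Fgf), 2742 bp (neurons), 2486 bp (heart muscle) and 2250 bp (red blood cells). The epithelium median lay above the range of lists matched on CpG content (at most 3134 bp) and was called higher in the pooled list (adjusted permutation p = 0.027) and with a 10000 bp window (0.0036), as the forebrain median was with that window (0.0036). Neither was called in a replicate's own list, where the epithelium excess fell from 714 bp to 557 bp without replicate 1 and 403 bp without replicate 2, and the forebrain excess went from 327.5 bp to 352 and 152.5 bp.

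**Figure D3:**
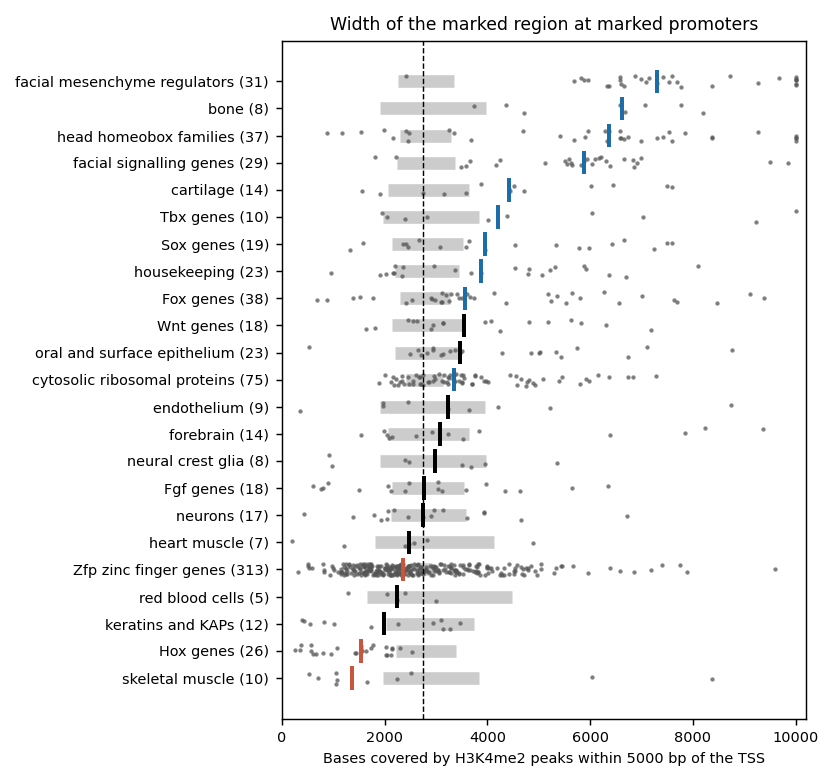
Bases covered by H3K4me2 peaks within 5000 bp of the TSS (horizontal axis, bp) for each marked member of a gene list (points; number of marked members in brackets), with the list median as a vertical bar (blue higher, red lower, black no call). Grey bands show the central 95% of medians of random lists of the same size, and the dashed line marks 2750 bp, the median of all marked genes; the facial mesenchyme median of 7295 bp lies farthest to the right.

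After joining peaks up to 1000 bp apart, the longest region across a TSS was at Pou3f3, on chromosome 1 from 42683768 to 42715015 (31248 bp). It was followed by Tbx3 (28852 bp), Hand2 (26531 bp), Ebf3 (25601 bp), Nr2f2 (25447 bp), Trps1 (24816 bp), Meis2 (24452 bp) and Epha4 (21689 bp). Dlx1 and Dlx2, a convergent pair of homeobox genes that pattern the jaw, shared a region of 21401 bp on chromosome 2 from 71525904 to 71547304. In the replicates' own lists the Pou3f3 region measured 31034 ± 105 bp (SD, n = 2) and the Tbx3 region 28651 ± 195 bp, while the region at Dlx1 measured 15280 ± 7991 bp, since gaps longer than the joining limit divided it near the middle in replicate 2 and cut off its left end in replicate 1. Of these 10 genes, Hand2, Meis2, Dlx1 and Dlx2 belonged to the facial mesenchyme list. All but Epha4, an ephrin receptor gene, encode transcription factors.

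The Hoxd cluster on the same chromosome held no peak as long as the longest at Dlx1 and Dlx2. In the 120 kb from 74656726 to 74776725 the replicated list held 23 peaks with a longest peak of 2020 bp, whereas in 120 kb around Dlx1 and Dlx2 it held 14 peaks with a longest peak of 9085 bp. The median peak lengths were 687 bp and 660 bp. The bases covered were 19203 in the Hoxd window and 23337 in the Dlx window. In replicate 1's own list the longest peaks were 9083 bp in the Dlx window and 1725 bp in the Hoxd window. In replicate 2's own list they were 5861 bp and 1778 bp. Dlx1 and Dlx2 stood among the longest regions and the Hox list was called narrow. The contrast therefore illustrates those results and is not a further test.

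**Figure D4:**
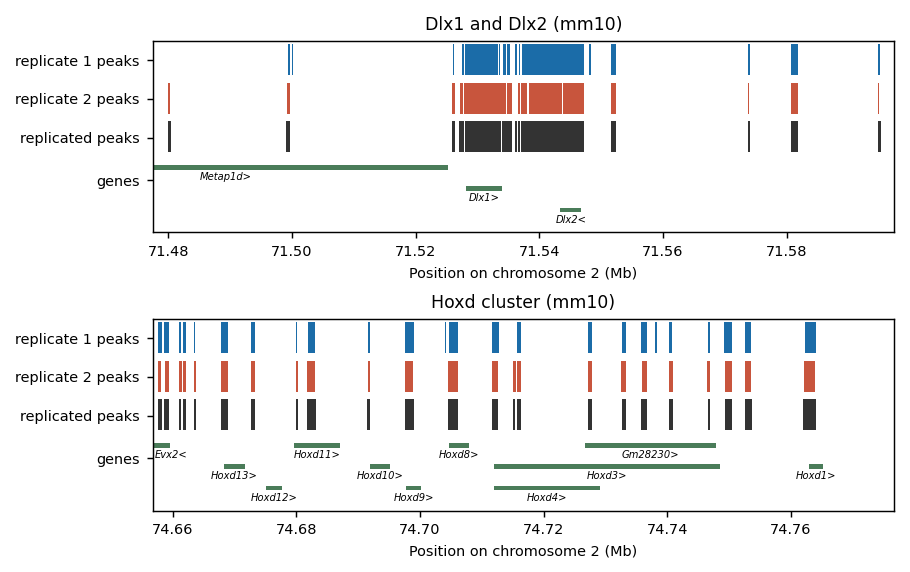
H3K4me2 peaks of replicate 1 (blue), replicate 2 (red) and the replicated list (black) over protein-coding genes (green, arrowheads give the strand) in 120 kb of chromosome 2 around Dlx1 and Dlx2 and in 120 kb around the Hoxd cluster (horizontal axes, position in Mb, mm10). Peaks over Dlx1 and Dlx2 joined into a region of 21401 bp, and the longest peak in the Hoxd window measured 2020 bp.

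Distal peaks numbered 15512, or 36.9% of the replicated peaks on assembled chromosomes, with a median enrichment of 4.66 and a median length of 641 bp. The most enriched ones reached the level of promoters. The first lay on chromosome 9 from 77654801 to 77656137, 18301 bp from the TSS of the nearest gene, Klhl31, in an exon (enrichment 65.1). The second lay on chromosome 13 from 42915870 to 42917622 in an intron, 235247 bp from the nearest TSS, that of Phactr1 (64.2). The third lay on chromosome 17 from 23699023 to 23700547 in intergenic sequence, 14997 bp from the TSS of Cldn9 (62.6). The fourth lay on chromosome 11 from 97546101 to 97547538 in an intron, 28648 bp from the TSS of Srcin1 (61.6). The fifth lay on chromosome 17 from 87745057 to 87747010 in an exon, 50984 bp from the TSS of Kcnk12 (59.7). Within the replicates' own lists the Klhl31 peak had enrichments of 59.3 and 57.8.

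Of the 14 consensus sequences counted in distal peaks, 4 were denser relative to flanks than every rearrangement of their letters. The nuclear factor I (NFI) consensus TTGGCNNNNNGCC had a ratio of 2.86, against a median of 1.55 and a highest value of 2.23 over 100 rearrangements. The TEAD consensus GGAATGT had a ratio of 1.27 (median 0.77, highest 1.15) and the forkhead (FOX) consensus TGTTTAC a ratio of 1.15 (median 0.80, highest 1.10). The homeodomain consensus TAATTA had a ratio of 0.87, below even density, but all of its 13 usable rearrangements were lower (median 0.61, highest 0.75). The core CTCF consensus had a ratio of 9.18 and was matched by 1 of 94 rearrangements, and it passed all of them in the pooled list and without replicate 2. The E-box CAGCTG had a ratio of 1.75, with 3 of 41 rearrangements at or above it. The remaining consensus sequences, for AP-2, the E-box CAGATG, SOX, RUNX, GATA, AP-1, ETS and HNF4, had between 9 and 70 rearrangements at or above them. Distal peaks had a GC content of 50.2% and flanks 44.5%. These ranks carry no p-value.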

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

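Peaks outside the assembled chromosomes were not part of any comparison. The replicated list held 15 of them, on 6 unplaced or unlocalized scaffolds, and they are listed here only because they lie in data left unused. The largest group, 6 peaks, lay on an unlocalized scaffold of chromosome X.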

How the results depend on the processing

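Of the recomputed counts and shares, 40 kept to within 1.5 times the count or 1 SD of the share, and 8 did not. The share of shared peaks fell to 64.2% when at least 50% of both peaks had to overlap and to 75.7% for 50% of either, as stricter rules must. Rho rose to 0.95 with 50% of both, over fewer and better matched peaks. The spread used for rho was the difference between matching from replicate 1 and from replicate 2 (0.84 and 0.87). The promoter share of peaks was 44.5% with a 2500 bp window and 47.4% with all annotated genes, both by a wider definition, 29.7% in the pooled list, which holds more weak peaks, and 33.5% to 33.8% with either replicate left out. Marked genes numbered 14038 to 15013 over all settings.

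Among single lists and motifs, 320 of the recomputed values kept their direction and side of the threshold, 19 passed it newly, 6 no longer passed and 16 changed sign, none of which was past the threshold before or after. At the TSS these were endothelium (-8.78 percentage points against other genes, then 1.81 with a 2500 bp window, 2.76 in the pooled list and -9.13 to 3.30 with either replicate left out), Hox (1.64, then -1.27 to 3.79 with either left out) and heart muscle (-21.3, then 0.23 at any transcript's TSS). By covered length against all marked genes they were red blood cells (-500 bp, then 1125 bp with a 10000 bp window and 13 bp in the pooled list), glia (241.5 bp, then -320 bp in the pooled list and -327 to -278.5 bp with either replicate left out), endothelium (484 bp, then -21 to 481 bp with either left out), Fgf (9.5 bp, then -100.5 to -10.5 bp with either replicate left out), neurons (-8 bp, then -29 to 206 bp with either left out and 23.5 bp with no neighbouring TSS) and keratins (-751 bp, then 362 bp with no neighbouring TSS). The Sox, Tbx, cartilage, housekeeping and ribosomal widths were those lost. The facial mesenchyme calls held in every setting tried. The motifs above every rearrangement numbered 4 or 5, and 3 under the first limit of 20 usable rearrangements, which left out the homeodomain consensus; the limit of 5 was chosen after the first run. Read depth was not analysed here, so how much of the weak end of the lists it limits is unknown. No paired analysis was possible because there was 1 group.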

Other observations

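The matches on CpG content for single lists, the restriction to members with no other TSS within 10000 bp, the split of the Hox genes, the regions without a protein-coding TSS and the match on nearby TSSs were chosen after the data were seen. The other tests here were written down before their results were seen, except the distal peak counts of lists other than facial mesenchyme, for which no prediction was written.

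Hox genes stood apart from promoters of like CpG content. Of 39 Hox genes 26 were marked, 66.7%, and random lists matched on CpG content gave 82.1% to 94.9% in the central 95%. The clusters differed in count, with 8 of 9 Hoxd, 8 of 11 Hoxa, 6 of 9 Hoxc and 4 of 10 Hoxb genes marked. At any transcript's TSS the counts were 8, 9, 7 and 6, or 30 of 39 in all (76.9%), and no matched range was computed for that definition. These differences between clusters were not tested. Marked genes were found along the whole series, in 7 of 12 genes numbered 1 to 4, 8 of 11 numbered 5 to 8 and 11 of 16 numbered 9 to 13. Some gene records have 5′ ends close together, so a single peak can count for several genes. Hoxd3 and Hoxd4 had the same covered length and enrichment (2139 bp, 11.8), as did Hoxc5 and Hoxc10 (565 bp, 3.57). The median enrichment over marked genes was 15.2 in Hoxa, 14.2 in Hoxd, 5.29 in Hoxb and 3.57 in Hoxc. The highest values were at Hoxa1 (50.9), Hoxd1 (45.1) and Hoxa7 (35.1), and Hoxc6 reached 30.9. Of the genes numbered 1 to 4, Hoxa2, Hoxb1, Hoxb2, Hoxb3 and Hoxc4 had no TSS peak in the replicated list. Hoxa2 had 1 in replicate 2's own list, and Hoxb3 and Hoxc4 had a peak at another transcript's TSS.

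Several long regions contained no protein-coding TSS. The longest, 12215 bp on chromosome 9 from 41578119 to 41590333, covered the microRNA gene Mir125b-1 and its host transcript. A region of 10706 bp on chromosome 7 from 142571461 to 142582166 covered the imprinted noncoding RNA gene H19 and Mir675. A region of 10666 bp on chromosome 14 from 61679604 to 61690269 lay at Dleu2. By chromosome, peaks were densest on chromosome 11, at 25.9 per Mb, and sparse on chromosome X, at 5.82 per Mb, and chromosome Y held 10. Chromosome 11 held 1637 protein-coding genes in 122 Mb and chromosome X 948 in 171 Mb. The densities were not adjusted for gene density or for the copies of the sex chromosomes in male and female embryos.

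White cell, liver and germ cell genes had few marked promoters, 3 of 48 or 6.25%. CpG content was weighed because promoters poor in CpG are often unmarked. Random lists matched on CpG content had marked shares of at least 33.3% in the central 95%, so CpG content alone did not account for the pattern. Of the 7 lists called lower, 6 lay below their matched range, and red blood cell genes lay inside theirs. No biological explanation was tested, since the series holds no other tissue. A tissue with few such cells would also give few peaks, and that stays open.

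The wide regions at facial mesenchyme regulators, 7295 bp, were set against CpG content and neighbouring genes. Random lists of marked genes matched on CpG content reached at most 3395 bp in the central 95%, and the 30 members with no other protein-coding TSS within 10000 bp had a median of 7358.5 bp, where random lists of such genes gave 2128 to 3163 bp. Within their limits, neither test accounted for the width. CpG content was matched only within 1000 bp of the TSS, so CpG-rich sequence reaching farther out was not set aside. Only the 5′ ends of protein-coding genes counted as neighbours, so noncoding genes and other transcripts' TSSs were not set aside either. Another candidate explanation is that width follows the activity of these genes in this tissue. That was not tested, since the series holds neither expression nor another tissue. Wide regions also occurred in the forebrain list, at Emx2 (9374 bp), Bcl11b (8244 bp) and Six3 (7849 bp). The median of the forebrain list was 3078 bp and was not called.

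Peaks called in 1 replicate only may be weak peaks near the calling threshold. Of the 27087 peaks in the upper 25% by enrichment of each replicate, both together, 0 (0.0%) lacked a partner. A second explanation, that the same stretch of signal was divided differently between the replicates, stays undecided. Of 22459 unshared peaks, 41.2% lay within 1000 bp of a peak of the other replicate, against 5.98% of randomly placed peaks, so it could cover part of them but not the rest. No biological explanation was tested.

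A further hypothesis was that there are more distal peaks around these genes than around other marked genes, for the facial mesenchyme regulators. They had a median of 6 distal peaks within 100000 bp of the TSS, against 1 for all marked genes and at most 2 in the central 95% of random lists (adjusted p = 1.5e-04, permutation test), which is consistent with the hypothesis. These genes have fewer annotated TSSs nearby, a median of 12 against 22, which leaves more sequence that counts as distal. Random lists matched on that number also gave 0 to 2. Parts of a gene's own wide region over 5000 bp from any TSS were counted as distal, so this count is not independent of width. Members close together, such as Dlx1 and Dlx2 (8 and 9 distal peaks), can also count the same peaks. Bone genes (median 5), signalling genes (4), the homeobox families of the head (4) and Wnt genes (4) were also above random lists of their size. So were forebrain genes (3, against at most 2 in the central 95%), with an adjusted permutation p of 0.056. Skeletal muscle, endothelium, Fgf and ribosomal protein genes had a median of 1. In the homeobox families, 20 members also belonged to the facial mesenchyme list, as did 2 bone genes.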
